A study of Mus musculus with 111 samples.

How the data were processed

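The data were estimated counts per transcript from single mouse 2-cell embryos. Per the labels, germinal vesicle oocytes were injected with a set of 2 siRNAs at 20 µM each and with 150 ng per µl of marker RNA, which coded for histone H2B fused to EGFP in control and to rsEGFP in target injections. They were kept in arrest medium for 5 hours, matured for 12 hours, fertilized in vitro and cultured in KSOM. Libraries were made from each embryo with the SmartSeq2 protocol and oligo dT priming, per the labels, so they hold polyadenylated RNA, carry no molecular identifiers and do not record the strand. Overlapping genes on opposite strands can therefore share reads. The design text names 55 Nr5a2 knockdown and 57 control embryos. Here 55 and 56 were analysed, in 6 groups formed by experiment (1 to 3) and arm, with the arm taken from the treatment label and the experiment and embryo number from the title. Control embryo 1 of experiment 2 was not analysed here.

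The submitters' processing notes list bcl2fastq, Trim Galore 0.6.2, kallisto 0.46.1, R 3.5.1 and DESeq2 1.32.0, and the builds mm10 and hg19 without a role. The annotation release behind the transcript index is not given in the sources used here. The main table holds the authors' deposited estimated counts (expected counts) per transcript, not normalized, per the file headers and the values. A second table holds values that the authors adjusted for batch and rounded, used here as a score with no stated method and only as an alternative. The authors' deposited comparison tables give log2 fold changes and adjusted p-values per transcript from DESeq2, one over all embryos and one under a 10th percentile threshold whose meaning is not given in the sources used here. In both authors' deposited tables the sign of the log2 fold change is knockdown over control, judged from the Nr5a2 and marker rows, and the test statistic has the opposite sign in 100% of rows. The authors' deposited tables call 45 transcripts lower and 92 higher over all embryos and 116 and 120 under the threshold. A table of normalized values was not used here, because its scaling is not stated.

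The 119353 transcripts were summed to genes. For 117282 of them the gene came from the authors' deposited table, for 345 from GENCODE M21, and 1726 without a gene were left out of library sizes and tests, with a median of 0.567% of the counts (0.459% to 0.711% over embryos). The sums gave 36134 gene identifiers, and were rounded to whole numbers. Rows for B1 and B2 repeats and 1 row under the Nr5a2 gene identifier were kept in the fit as separate features and are not counted among the genes, and the 2 reporter rows were kept out. No per-sample column was left unmatched. Of 35820 genes, 2.97% had the same start and end in the deposited table as in GENCODE M21, so positions are given from GENCODE M21 (GRCm38) only. No 2 libraries were identical, and the highest Pearson's r between 2 embryos over log2 CPM was 0.941, so no library was counted more than once. Each embryo was taken as 1 sample, which assumes that embryos of the same experiment and arm are independent.

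Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr by arm, TMM scaling, and the quasi-likelihood F-test of knockdown against control with experiment as a factor, over 13448 genes with 107 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes, except those of the reporter rows, which use the total over genes. The biological coefficient of variation was 0.616. SEs of log2 fold changes were taken from the fold change and the F statistic. The same model with treatment-by-experiment terms tested whether responses differ between experiments, and a fit over 25256 transcripts gave 22 lower and 56 higher transcripts. The 23 gene lists were tested with camera (preset correlation, adjusted over the lists), with camera under an estimated correlation, and with fry, and members were also adjusted over the list alone.

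The test design, the gene lists, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took Nr5a2, then the 14 lower and 10 higher called genes with the largest fold change, 1 sign in all 3 experiments, an average log2 CPM of at least 4 and a symbol that is not a clone name, the 3 genes with the smallest p in each direction, and for each list up to 2 called members per direction or else the member with the smallest p. It named 50 genes, 31 of them called. H2bc21 and Prr15 were named because the interaction test called them, and the members that passed over their list alone and the partners of Lrtm1 were chosen after their values were seen.

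The 2-cell score of an embryo was the mean log2 CPM (prior count 2) of the measured members of the 2-cell list. Differences between arms were tested with 100000 permutations of the arm within experiments, two-sided, and the smallest p they can give is 1e-05. Genes detected were counted at 1 count or more after thinning each library to 2747197 counts, the level that keeps 95% of embryos, which left 55 control and 51 knockdown embryos. Correlations were computed within each experiment and arm, with exact enumeration in the group of 7. Scores and permutations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

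The tests were checked on simulated counts drawn from the means, dispersions and library sizes of the real genes, with 200 changed genes. In the comparison of knockdown with control, over 13149 simulated genes that passed the filter, edgeR called 92 of 97 genes changed by 2-fold and 45 of 98 changed by 1.5-fold, with 7 false calls among 144. limma-voom called 88 and 43, and DESeq2 called 95.9% and 52.0%. In the interaction test, over 13135 genes, 25 of 98 genes changed by 2-fold in experiment 1 alone were called, and 2 of 98 changed by 1.5-fold. A list of 40 genes raised by 1.25-fold was called by camera and 0 of 20 unchanged lists were, but those simulated genes were independent of each other, unlike genes in embryos.

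The alternatives changed 1 choice at a time, apart from what a choice brings with it: DESeq2 used its own size factors, the block held the 92 embryos whose number occurs in both arms of an experiment, and the filter was applied anew to the sums (21532 genes) and to each subset. They were median-of-ratios size factors, factors from the oocyte list, library totals alone, other low-count filters, DESeq2 1.42.0, limma-voom, no experiment term, a block of experiment and embryo number, the number of genes detected as a term, sums per experiment and arm, each experiment left out or fitted alone, the authors' batch-corrected values, and transcripts as features. A further 5 were added after the data were seen: the first principal component, the library total or a Y-linked level as a term, scaling without mitochondrial transcripts, and the fit without the knockdown embryo short of reporter counts. For a tested value, a change of sign is counted as a reversal only where the reported value or the alternative passed the threshold.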

Results

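Polyadenylated RNA was sequenced from single mouse embryos of strain B6129F1 at the 2-cell stage, the stage of the main wave of zygotic genome activation in this species. The embryos came from fully grown oocytes that had been injected, still arrested in prophase of meiosis, with siRNAs against Nr5a2 or with control siRNAs, then matured and fertilized in vitro. Nr5a2 encodes an orphan nuclear receptor that binds DNA as a monomer. Experiment 1 held 24 control and 16 knockdown embryos, experiment 2 held 7 and 16, and experiment 3 held 25 and 23, which made 56 control and 55 knockdown embryos. Library totals ran from 1.97 to 21.4 M estimated counts with a median of 4.78 M. The median total was 4.98 M in control and 4.54 M in knockdown embryos. Levels are in counts per M (CPM). Each library came from 1 embryo, so p-values measure the spread between single embryos, and the labels do not say which embryos shared a mother.

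The first question was how much Nr5a2 RNA remained at the 2-cell stage after the injection. Nr5a2 fell in the knockdown embryos of all 3 experiments, from 109 ± 48.9 CPM (SD, n = 56) in controls to 48.6 ± 19.8 CPM (SD, n = 55). The log2 fold change was -1.17 (SE 0.12; edgeR quasi-likelihood test, adjusted p = 3.7e-12), the smallest p of any gene. It was -1.29 (SE 0.18) in experiment 1, -1.13 (SE 0.28) in experiment 2 and -1.07 (SE 0.20) in experiment 3. In 52 of the 55 knockdown embryos Nr5a2 lay below the median control embryo of the same experiment. Knockdown embryos ranged from 13.1 to 119 CPM and control embryos from 32 to 234 CPM, so the arms overlapped and RNA of the target was detected in every embryo. When experiment 2, with 7 control embryos, was fitted alone with edgeR, the fold change stayed at -1.13 but the adjusted p over all genes was 0.513.

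**Figure D1:**
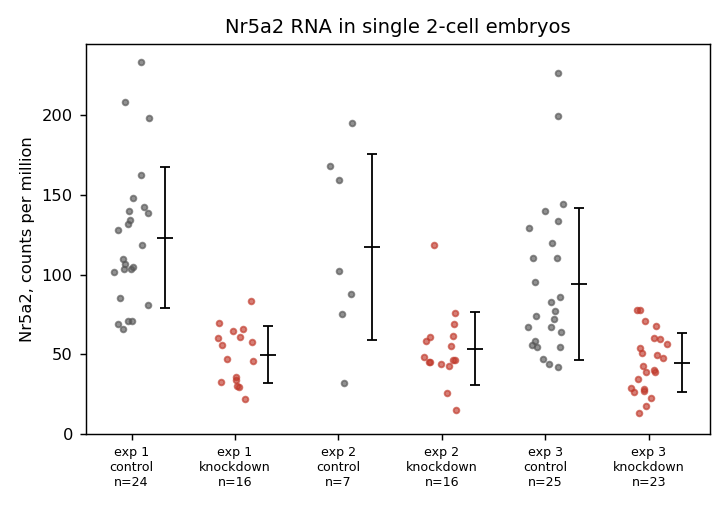
Nr5a2 RNA in CPM (vertical axis) in each single embryo, by experiment and arm (horizontal axis), with the mean and SD of each group as a bar beside the points. Group means are 123, 117 and 94.2 CPM in the controls of experiments 1, 2 and 3 and 49.5, 53.5 and 44.7 CPM in the knockdown embryos.

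The gene (ENSMUSG00000026398) lies on chromosome 1 from 136842571 to 136960448, minus strand, in the GRCm38 annotation GENCODE M21, and 4 of its annotated transcripts passed the expression filter. The most abundant, ENSMUST00000192929.5, fell from 52.4 ± 23.8 (SD, n = 56) to 17.3 ± 11.5 CPM (SD, n = 55), a log2 fold change of -1.69 (SE 0.17, edgeR adjusted p = 1.2e-12). ENSMUST00000192357.5 fell as well, by 1.30 on the log2 scale (SE 0.29, adjusted p = 0.0133). ENSMUST00000168126.6 had a log2 fold change of -1.76 (SE 0.55) that did not pass the test at 8.97 CPM in controls (adjusted p = 0.192). ENSMUST00000027649.13 was at 18.5 ± 10.2 CPM (SD, n = 56) in controls and 16.5 ± 9.61 CPM (SD, n = 55) in knockdown embryos, a log2 fold change of -0.087 (SE 0.20, adjusted p = 0.9999), so no difference in the counts assigned to this transcript was detected. The authors' deposited table over all embryos gave -1.56 for ENSMUST00000192929.5, -1.34 for ENSMUST00000192357.5, -1.31 for ENSMUST00000168126.6 and -0.093 for ENSMUST00000027649.13.

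The second question was which other genes differed between the arms. Of 13448 genes tested, 63 were lower and 85 higher in knockdown embryos at an adjusted p under 0.05, which is 1.10% of them, with 1278 at an unadjusted p under 0.05, and 6 of the lower and 7 of the higher genes changed by at least 2-fold. Of the called genes, 55 of the 63 lower and 68 of the 85 higher had 1 sign in all 3 experiments fitted apart. The same embryos gave the calls, so this count is no separate test. The median log2 fold change over all genes was 0.019. Scaling by the library total alone gave 69 lower and 58 higher genes, so the share of higher genes among the calls was 45.7% in place of 57.4%. Size factors from the oocyte list left 11 lower and 18 higher genes, with 9 of the 30 called genes named here besides Nr5a2, and summing the counts by experiment and arm, 3 sums against 3, left 1 lower and 2 higher genes, while there were 391 and 574 without a low-count filter and 219 and 141 with the first principal component as a term. With 1 experiment left out, there were 9 lower and 14 higher genes without experiment 1, 59 and 136 without experiment 2, and 11 and 31 without experiment 3. Of those 30 named genes, 7 passed without experiment 1, 24 without experiment 2 and 8 without experiment 3. Some folds stayed of like size: Parp1 had -0.70 (SE 0.21, edgeR adjusted p = 0.210) without experiment 1, against -0.65 (SE 0.15) with it. Others were smaller outside experiment 1: Fermt3 had 1.17, 0.51 and 0.22 in experiments 1, 2 and 3. Over the 105 genes called in experiment 1 alone, without H2bc21, the median log2 fold change signed by experiment 1 was 0.91 there. It was 0.23 in experiments 2 and 3. These genes were chosen by their calls in experiment 1, which raises the 0.91. The drop to 0.23 therefore does not show a weaker response in the other experiments. The reason for the lost calls was not tested.

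The largest decrease among the named genes besides Nr5a2 was in Zfp599, a zinc finger protein gene, from 171 ± 76.0 (SD, n = 56) to 90.3 ± 53.3 CPM (SD, n = 55), a log2 fold change of -1.01 (SE 0.17, edgeR adjusted p = 5.4e-05) seen in 50 of the 55 knockdown embryos against the control median of their experiment. Sox15, an HMG-box transcription factor gene, fell by 0.84 on the log2 scale (SE 0.21, adjusted p = 0.0157), and Ptger4, a receptor for prostaglandin E, by 0.82 (SE 0.20, adjusted p = 0.0135). Rffl, an E3 ubiquitin ligase gene, fell by 0.79, Tmem191c by 0.71 and Rgs11, a regulator of G protein signalling, by 0.69. Among enzymes, the genes that fell included Pcyt2 of phosphatidylethanolamine synthesis (-0.69, in 50 of 55 embryos), the kynurenine aminotransferase gene Kyat3 (-0.68), the glucosamine-phosphate deaminase gene Gnpda1 (-0.62) and the xylulokinase gene Xylb (-0.62). Parp1, which adds poly(ADP-ribose) at DNA breaks, fell from 66.5 ± 42.4 (SD, n = 56) to 47.1 ± 28.6 CPM (SD, n = 55), a log2 fold change of -0.65 (SE 0.15). Jade1, part of a histone acetyltransferase complex, fell by 0.62 (SE 0.12, adjusted p = 6.8e-04), and Iqub fell by 0.67. The fold change of Sox15 in experiment 2 was -0.053.

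The named genes that rose were led by Lrtm1, which encodes a membrane protein with leucine-rich repeats, and Pam, which encodes the enzyme that amidates peptide hormones. Over all called genes the largest absolute log2 fold change was 2.15, in a gene that the naming rule did not take. Lrtm1 (chromosome 14, 29018208 to 29033645, plus strand, GRCm38) went from 104 ± 88.4 (SD, n = 56) to 226 ± 300.2 CPM (SD, n = 55), a log2 fold change of 1.39 (SE 0.16, edgeR adjusted p = 4.8e-11). Pam (chromosome 1, 97795114 to 98095646, minus strand, GRCm38) went from 109 ± 88.8 (SD, n = 56) to 214 ± 252 CPM (SD, n = 55), a log2 fold change of 1.31 (SE 0.15, adjusted p = 2.8e-10). Both were above the control median of their experiment in 49 of 55 knockdown embryos. Their base level differed between experiments: control embryos had 176, 7.36 and 61.6 CPM of Lrtm1 and 175, 6.67 and 74.7 CPM of Pam in experiments 1, 2 and 3. Poglut3, a protein O-glucosyltransferase gene, rose by 1.02 (SE 0.24, adjusted p = 0.0130), and Cdh6, a classical cadherin gene, by 0.94 (SE 0.14, adjusted p = 9.8e-07), although its fold change in experiment 2 was 0.10. The zinc finger gene Zfp101 rose by 0.81 and the alpha-kinase gene Alpk2 by 0.75, with 0.17 and 0.081 in experiment 2. The kindlin gene Fermt3 rose by 0.62, the structure-specific endonuclease gene Slx1b by 0.61, the magnesium transporter gene Mmgt2 by 0.60 and Adam22 by 0.59. Counts of Dock10, the gene of an exchange factor for small GTPases and the most abundant of these genes, rose from 3456 ± 1407 (SD, n = 56) to 4870 ± 3084 CPM (SD, n = 55). The log2 fold change was 0.61 (SE 0.10, adjusted p = 1.2e-05), with 1.04 in experiment 1, 0.13 in experiment 2 and 0.49 in experiment 3. Of the Dock10 counts, 99.9% fell on 1 annotated transcript of 1899 bases. Whether this transcript encodes the exchange factor was not examined.

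**Figure D2:**
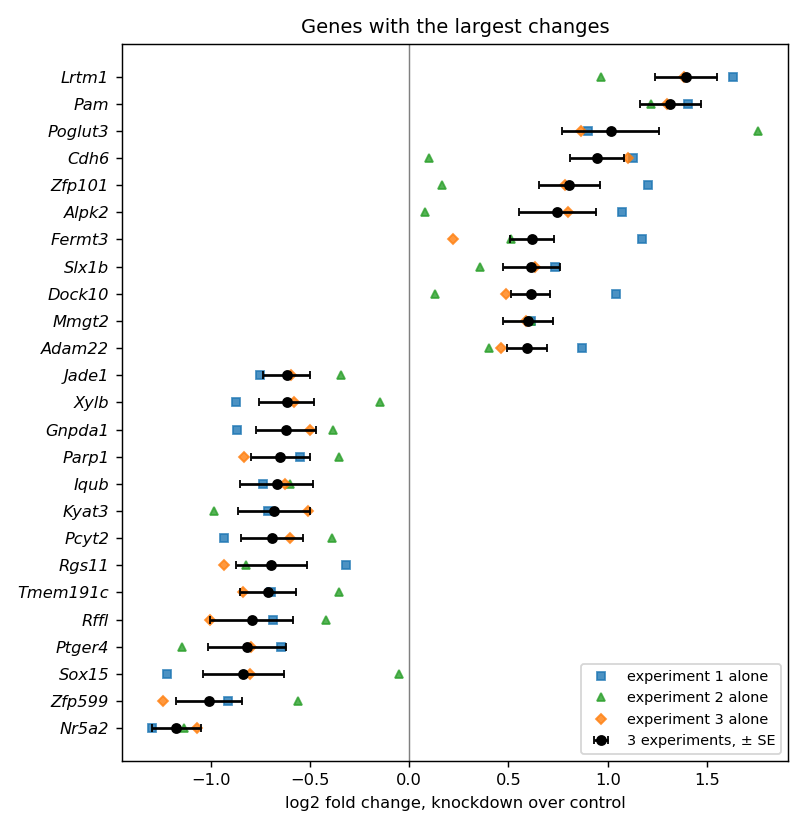
Log2 fold change of knockdown over control (horizontal axis) for the genes named by size or p (vertical axis), with the fit over 3 experiments and its SE in black and each experiment alone in colour. Nr5a2 lies lowest at -1.17 and Lrtm1 highest at 1.39, and in experiment 2 alone Sox15 lies at -0.053 and Cdh6 at 0.10.

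Transcripts typical of the 2-cell stage were the group of first interest, since they are among the RNAs made in the wave of genome activation. The list holds genes with transient high expression at this stage, so it does not measure genome activation as a whole. None of the 38 measured members of the 2-cell list, among them Zscan4, Tdpoz, Usp17l and Zfp352 transcripts, passed the edgeR test over all genes or adjusted over the list alone. In this list 24 members had a negative and 14 a positive fold change, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. The mean log2 fold change was -0.064 (SD 0.20 over members; camera adjusted p = 0.275), and the member with the smallest p, Tdpoz5, was at 278 ± 121 (SD, n = 56) and 225 ± 109 CPM (SD, n = 55), a log2 fold change of -0.36 (SE 0.15, adjusted p = 0.349). Several families in this list have near-identical copies, so the split of counts among their members is uncertain. In tests on simulated counts a change of 2-fold was called for 94.8% of genes and one of 1.5-fold for 45.9%, so losses of 2-fold in single members of typical expression were within reach, and smaller ones were not reliably detectable.

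The level of the whole 2-cell list in an embryo varied widely within both arms. Its score, the mean log2 CPM of the 38 members, was 6.13 ± 0.75 (SD, n = 56) in control and 5.98 ± 0.80 (SD, n = 55) in knockdown embryos. The difference within experiments was -0.13 (SE 0.15, two-sided permutation p = 0.394), with -0.046, -0.057 and -0.23 in experiments 1, 2 and 3, so no difference was detected. The spread of the score between embryos did not differ detectably either, with an SD within experiments of 0.76 in control and 0.81 in knockdown embryos (permutation p = 0.711). Embryos with more remaining Nr5a2 did not have a detectably higher score. Over 6 correlations, 1 per experiment and arm, Pearson's r ran from -0.133 to 0.656 and no adjusted p was under 0.05. In the 23 knockdown embryos of experiment 3, r was 0.411 (permutation p = 0.0496, adjusted p = 0.297) and Spearman's rho 0.263 (p = 0.226, adjusted p = 0.452), and r was 0.300 without the 2 embryos farthest from the median Nr5a2 level. In the 7 control embryos of experiment 2, r was 0.656 (exact permutation p = 0.115, adjusted p = 0.317) and rho 0.750 (exact p = 0.0663, adjusted p = 0.398), and r was 0.880 without the 2 farthest (exact p = 0.0667). In the knockdown embryos of experiment 1, r was 0.238 (permutation p = 0.376) and 0.406 without the 2 farthest (permutation p = 0.147).

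Maternal and housekeeping groups gave no called member in the other 3 lists of first interest. The 48 oocyte-deposited transcripts, among them Gdf9, Zp3 and Dppa3, had a mean log2 fold change of 0.035 and a median of 0.024, while camera placed the list on the lower side (adjusted p = 0.647), so that the signs differ, and the mean was -0.090 with size factors from the list itself and -0.022 with library totals. No oocyte transcript had an unadjusted p under 0.05, and none was called by edgeR, DESeq2 or limma-voom, or adjusted over the list alone. Dppa3 was at 1236 ± 442 (SD, n = 56) and 1451 ± 547 CPM (SD, n = 55; log2 fold change 0.22, adjusted p = 0.57). The 87 cytosolic ribosomal protein genes had a mean of 0.064, with 60 of 87 positive (camera adjusted p = 0.275). By edgeR 0 were called, adjusted over the list alone too, with 6 at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. Factors of ribosome biogenesis ranked lower than other genes by camera (96 members, mean -0.032, adjusted p = 0.0211; adjusted p = 0.941 with an estimated correlation), but the mean was 0.034 and the call was lost with size factors from the oocyte list (adjusted p = 0.149). None of the 96 was called by edgeR, DESeq2 or limma-voom or adjusted over the list alone, 6 had an unadjusted p under 0.05, and the call of the list was lost without experiment 1 (mean -0.0032) and without experiment 3 (mean 0.014). In experiment 2 alone the list was called in the opposite direction (mean 0.18, camera adjusted p = 8.3e-07; adjusted p = 0.797 with an estimated correlation).

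Transcripts of the mitochondrial genome, a list fixed in advance as a sign of RNA quality, were higher in knockdown embryos, the same embryos in which the genes above were compared. All 13 had a positive fold change, with a mean of 0.29 (SD 0.11 over members; camera adjusted p = 4.5e-18, adjusted p = 0.0719 with an estimated correlation; fry adjusted p = 0.00753). By edgeR 6 of 13 rose over all genes tested and 11 adjusted over the list alone. mt-Nd2 rose from 2985 ± 1233 (SD, n = 56) to 3583 ± 1726 CPM (SD, n = 55), a log2 fold change of 0.44 (SE 0.09, adjusted p = 8.2e-04) seen in 47 of 55 embryos, and mt-Nd3 rose by 0.44 as well (SE 0.09, adjusted p = 0.00351), both subunits of respiratory complex I. Per embryo, the mean log2 CPM of the 13 transcripts differed by 0.27 within experiments (SE 0.07, permutation p = 2.1e-04). The difference was 0.16 in experiment 1 (permutation p = 0.276), 0.11 in experiment 2 (p = 0.444) and 0.44 in experiment 3 (p = 3e-05), and a permutation test of the difference between experiments gave p = 0.115. Without experiment 3 the mean fold change of the 13 was 0.15 (camera adjusted p = 0.00572; adjusted p = 0.923 with an estimated correlation), 0 of them passed by edgeR, and the score differed by 0.14 (permutation p = 0.181). As a share of all counts, mitochondrial transcripts made 7.41% ± 2.03 (SD, n = 56) in control and 8.00% ± 2.30 (SD, n = 55) in knockdown embryos. Such means, also those in CPM, pool experiments that hold unequal shares of the arms, unlike the fold changes. Within experiments the share differed by 1.03 percentage points (SE 0.38, permutation p = 0.00755), with 0.31, 0.34 and 1.88 in experiments 1, 2 and 3. Nuclear genes of oxidative phosphorylation leaned the same way by camera (78 members, mean 0.077, adjusted p = 0.0444; adjusted p = 0.941 with an estimated correlation), but 1 of 78 rose, Cox6b1 of complex IV (0.42, SE 0.12, adjusted p = 0.0484), also when adjusted over the list alone. The call of Cox6b1 was lost in 18 of 24 alternatives, with fold changes from 0.30 to 0.47 over the 24, and the list's call was lost without experiment 1 (adjusted p = 0.144), without experiment 3 (adjusted p = 0.155) and with library totals as the scaling (adjusted p = 0.0721).

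Cell cycle genes did not move as 1 group. Of 53 replication genes, thymidine kinase Tk1 fell from 196 ± 87.1 (SD, n = 56) to 142 ± 67.5 CPM (SD, n = 55), a log2 fold change of -0.52 (SE 0.14, edgeR adjusted p = 0.0341). Pola2, a subunit of the polymerase that starts DNA strands, rose by 0.51 (SE 0.13, adjusted p = 0.0320) and Rfc2, a clamp loader subunit, by 0.43 (SE 0.11, adjusted p = 0.0241). The same 3 passed when adjusted over the list alone, and the other 50 did not pass. In experiment 2 the fold changes of Pola2, Rfc2 and Tk1 were -0.34, -0.024 and -0.053. The 40 genes of G2 and mitosis had 30 negative fold changes and a mean of -0.082 (camera adjusted p = 8.8e-04; adjusted p = 0.941 with an estimated correlation). None of the 40 was called by edgeR, DESeq2 or limma-voom or adjusted over the list alone, 5 had an unadjusted p under 0.05, and the list's call was lost without experiment 1 (adjusted p = 0.144) and without experiment 3 (adjusted p = 0.0802).

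Regulators and lineage genes showed small counts. Adjusted over the list alone, Tfap2a passed in both the list of 41 regulators of genome activation and that of 26 trophectoderm genes (log2 fold change 0.44, SE 0.13, adjusted p = 0.0540 over all genes). Klf2 passed among 22 genes of pluripotency and the inner cell mass (0.64, adjusted p = 0.0721 over all genes). In the list of 30 stress genes, Chac1 was positive (0.83, adjusted p = 0.106 over all genes) and Pdia4 and Bag3 negative (-0.32 and -0.43) when adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, among 27 nuclear receptors, 14 primitive endoderm genes, 30 p53 targets, 13 interferon-response genes, 54 chromatin modifiers, 60 spliceosome genes, 36 proteasome subunits, 20 tRNA synthetases or 84 translation factors. Esrrb, an orphan receptor of the same superfamily as Nr5a2, was at 17.6 ± 9.93 (SD, n = 56) and 22.1 ± 13.6 CPM (SD, n = 55; 0.35, adjusted p = 0.498). None of these 13 lists was called by camera, and their mean log2 fold changes lay between -0.049 for primitive endoderm and 0.025 for regulators of genome activation. Over these lists with those of mitosis and of other cells, 16 in all, edgeR called 0 of 511 list entries, against 55 at an unadjusted p under 0.05, 8 called by DESeq2 and 3 by limma-voom.

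Markers of other cells gave no called difference. The 8 measured genes of cumulus and granulosa cells had a mean log2 fold change of 0.13 (camera adjusted p = 0.796) and the 6 of sperm 0.20 (adjusted p = 0.53). By edgeR 0 of these 14 genes were called, over all genes or adjusted over the list alone, with 0 cumulus and 1 sperm gene at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Serpine2, the cumulus gene with the smallest p, was at 57.9 ± 22.9 (SD, n = 56) and 66.3 ± 51.5 CPM (SD, n = 55). The number of genes detected per embryo, after thinning to 2747197 counts, was 17127 ± 610 (SD, n = 55) in control and 16935 ± 583 (SD, n = 51) in knockdown embryos, a difference within experiments of -123 (SE 118, permutation p = 0.299). Without thinning it was -260.3 (SE 132, permutation p = 0.0517).

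**Figure D3:**
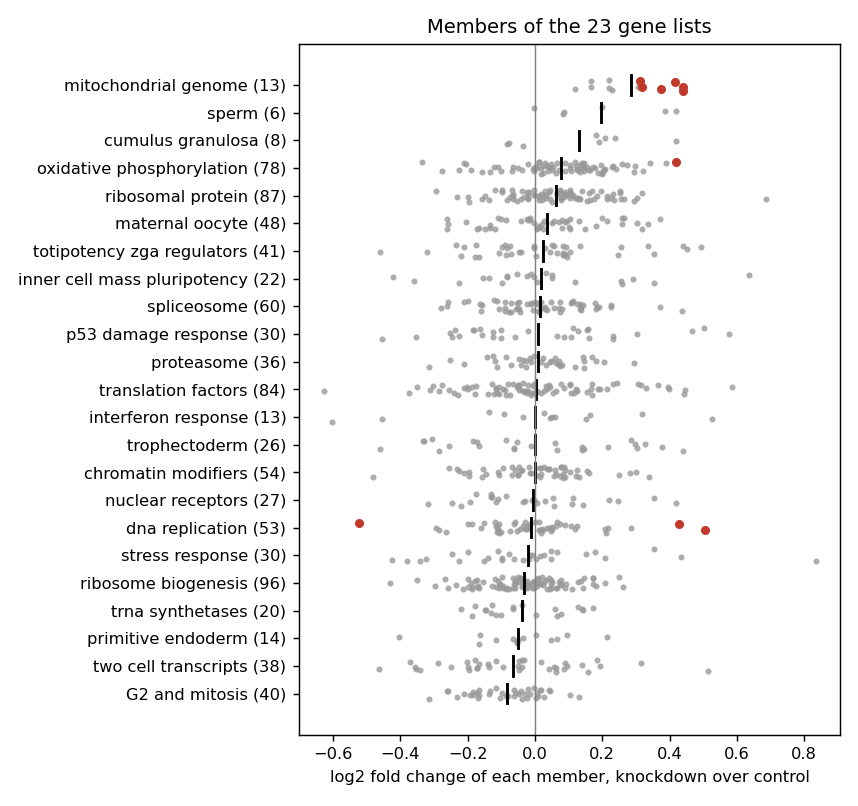
Log2 fold change of knockdown over control (horizontal axis) for each measured member of the 23 gene lists (vertical axis, number of members in brackets), with called members in red and the list mean as a black bar. All 13 mitochondrial genome transcripts lie above 0 and 6 are called, while the 38 transcripts of the 2-cell list spread over both sides of 0 with a mean of -0.064.

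**Figure D4:**
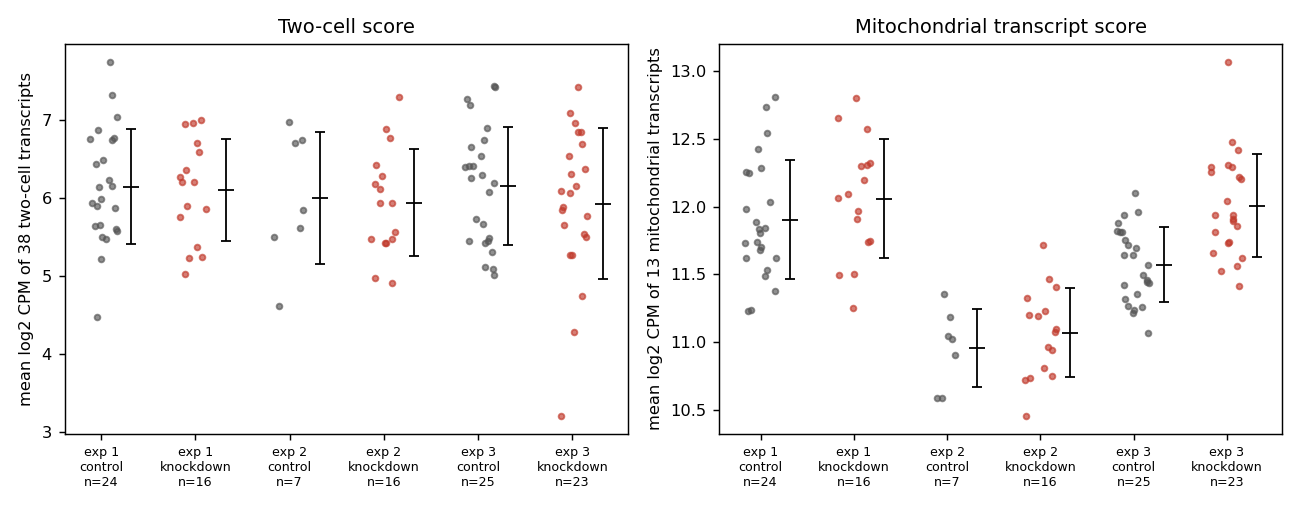
Mean log2 CPM of the 38 transcripts of the 2-cell list (left) and of the 13 mitochondrial transcripts (right) in each embryo (vertical axes) by experiment and arm (horizontal axes), with the mean and SD of each group as a bar. The 2-cell score differs by -0.13 within experiments and the mitochondrial score by 0.27.

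Short interspersed repeats were counted as 2 further rows. B1 was at 43.5 ± 15.2 (SD, n = 56) in control and 54.3 ± 22.3 CPM (SD, n = 55) in knockdown embryos, a log2 fold change of 0.31 (SE 0.10, edgeR adjusted p = 0.116), and B2 at 51.2 ± 29.4 (SD, n = 56) and 68.5 ± 35.6 CPM (SD, n = 55), 0.44 (SE 0.14, adjusted p = 0.101). Neither passed the test over 3 experiments. In experiment 2 the fold changes were negative, -0.11 for B1 and -0.32 for B2, and without experiment 2 they were 0.41 (adjusted p = 0.0370) and 0.62 (adjusted p = 0.00988). A further row under the gene identifier of Nr5a2, whose sequence is not given in the sources used here, had 48.1 ± 18.2 (SD, n = 56) and 52.0 ± 29.7 CPM (SD, n = 55; 0.19, SE 0.11, adjusted p = 0.632).

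The third question was whether the 3 experiments gave the same response. Of 13448 genes, 2 had a response that differed between experiments by the edgeR interaction test, with 760 at an unadjusted p under 0.05. H2bc21, a gene of histone H2B, had log2 fold changes of 6.00 (SE 0.50) in experiment 1, -1.24 (SE 0.59) in experiment 2 and -1.49 (SE 0.34) in experiment 3 (interaction adjusted p = 1.7e-18). Prr15 had 1.04 (SE 0.22), -0.73 (SE 0.31) and 0.32 (SE 0.16; interaction adjusted p = 0.0367). DESeq2 called 10 genes and limma-voom 1 in the same test. In simulated counts with a response in experiment 1 alone, the interaction test called 25.5% of genes changed by 2-fold and 2.04% of those changed by 1.5-fold. Most differences of 2-fold and nearly all of 1.5-fold would thus have been missed, so the few calls do not show that the experiments agree.

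The injected marker RNAs, which code for histone H2B joined to a fluorescent protein, left their own counts on 2 reporter rows. Per the labels, control embryos received one version of the protein and knockdown embryos another, so the marker differs between the arms along with the siRNA. In the controls of experiment 1, 1 of 24 embryos had at least 10 counts on row 1 and 0 had them on row 2, so the counts do not show which marker, if any, these embryos received. Reporter row 2 had medians of 142, 320 and 25.5 CPM in the knockdown embryos of experiments 1, 2 and 3, and at most 1.86 CPM in any control embryo. Reporter row 1 was not limited to controls, with medians of 21.3, 34.8 and 3.72 CPM in the knockdown embryos of experiments 1, 2 and 3. It had medians of 902 and 119 CPM in the controls of experiments 2 and 3 but a median of 0 CPM and at most 2.19 CPM in the 24 controls of experiment 1. H2bc21 had 1.30 ± 2.58 CPM (SD, n = 24) in these controls and 78.7 ± 43.3 CPM (SD, n = 16) in the knockdown embryos of experiment 1. Knockdown embryo 15 of experiment 3 had 2 counts on row 2 and 53.9 CPM of Nr5a2, and without it there were 64 lower and 80 higher genes.

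**Figure D5:**
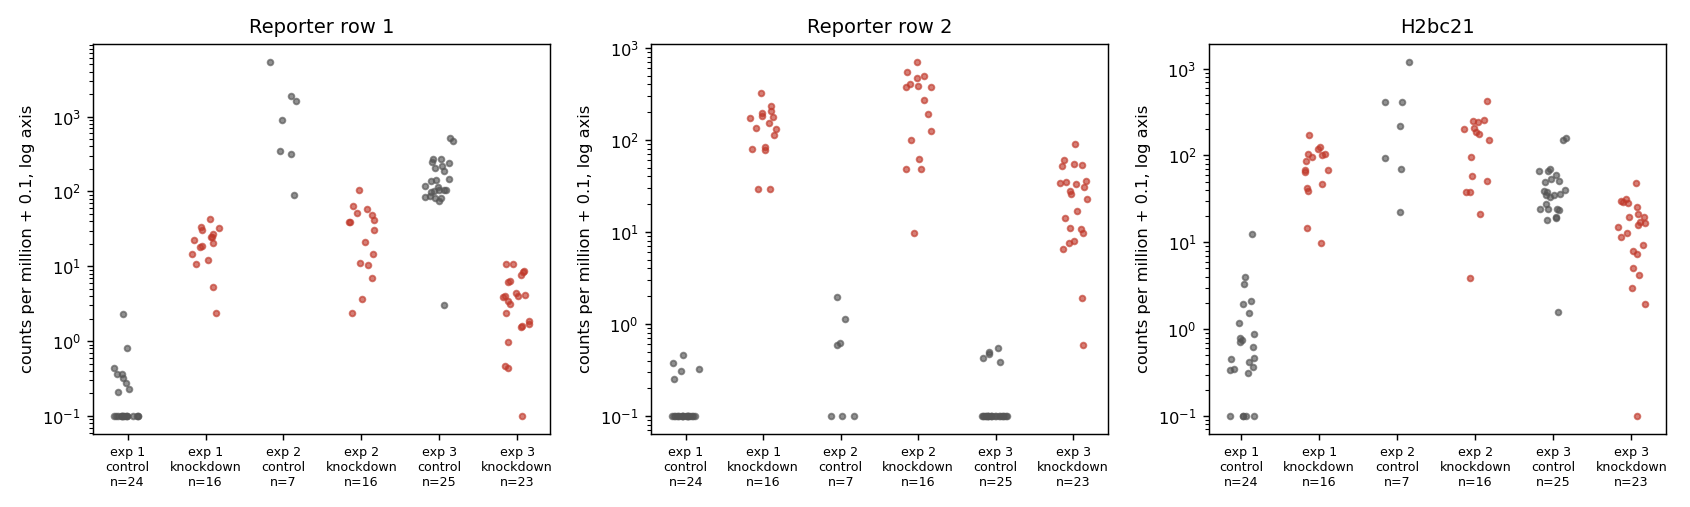
CPM plus 0.1 on a log axis (vertical axes) of reporter row 1, reporter row 2 and H2bc21 in each embryo, by experiment and arm (horizontal axes). Control embryos of experiment 1 have at most 2.19 CPM of row 1 and 12.4 CPM of H2bc21, while row 2 is found in knockdown embryos of all 3 experiments.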

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

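The tests of H2bc21 and of the mitochondrial transcripts were chosen after the results were seen, and the counts over other splits of the embryos and the test of the experiment 1 genes were set before.

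The response of H2bc21 differed between experiments (interaction adjusted p = 1.7e-18), with log2 fold changes of 6.00, -1.24 and -1.49 in experiments 1, 2 and 3. These signs and SEs leave no room for 1 common response of the gene in all 3 experiments, but that adjusted p is what singled the gene out and no separate test. The levels followed the injected marker: in the 5 groups with marker counts, log2 H2bc21 and the log2 total of the reporter rows had a lowest Pearson's r of 0.975 (experiment 3 knockdown, 23 embryos; rho 0.946; permutation p = 1e-05 for both, the smallest the permutations can give, adjusted p = 1.5e-05 over 6 groups), and 0.954 without the 2 embryos farthest from the median. In the controls of experiment 1, with almost no marker counts, r was 0.245 (permutation p = 0.231, adjusted p = 0.231; rho 0.187, p = 0.376). Reads of the injected H2B part assigned to H2bc21 are therefore a candidate explanation for this gene.

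Signals on the reporter rows stood outside the gene comparisons: row 2 had a median of 142 CPM in knockdown embryos of experiment 1, 320 CPM in experiment 2 and 25.5 CPM in experiment 3, each above the highest control embryo of the same experiment. Over the 105 genes called in experiment 1 alone, without H2bc21, the median log2 fold change signed by experiment 1 was 0.91 in experiment 1 and 0.23 in experiments 2 and 3, where 95 of 105 genes kept the sign. That is above the 0.16 that bounds 95% of permuted arms (10000 permutations, one-sided p = 0.00890) but below 0.30, the level set beforehand for excluding the near absence of marker row 1 from the controls of experiment 1, so this test did not decide. The 105 genes were chosen by their calls in experiment 1, which raises the 0.91 and the 0.30 derived from it.

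The 13 mitochondrial transcripts were higher in knockdown embryos, by 0.27 in mean log2 CPM per embryo. The missing marker in the controls of experiment 1 is argued against, since the difference without that experiment was 0.34 (SE 0.08, permutation p = 7e-05). Scaling between libraries and library size are argued against as the whole cause: the lowest mean log2 fold change under 4 other scalings was 0.25 and that with the library total as a term was 0.27, against 0.29 as reported, where the list was not called with an estimated correlation (adjusted p = 0.0719), and under the factors from the oocyte list mt-Nd2 went from 0.44 (SE 0.09) to 0.42 (SE 0.12) and no member passed, as the spread grew. A rise limited to experiment 3 stays open, as the difference without it was 0.14 (SE 0.10, permutation p = 0.181) and the test between experiments gave p = 0.115. The siRNA, the type of marker protein and handling of each arm are confounded by the design and may each contribute, and a response to Nr5a2 is 1 untested hypothesis among these.

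Prr15 was the other gene whose response differed between experiments (interaction adjusted p = 0.0367), with 1.04, -0.73 and 0.32. One far value was found in 5 measures tested in the only group of 10 or fewer embryos: control embryo 2 of experiment 2 had a total of 2.15e+06 counts over genes (2154821), against 3460903 to 4058882 in the other 6, and chance gives about 1 such value in 20 groups for each of the 5 measures, so more often over all 5.

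A chance split of single embryos is argued against for the count of 148 genes called between the arms. Of 100 splits of the embryos within experiments, 1, the real one, gave as many, and the highest of the others gave 58. Such splits treat the embryos of an arm as independent. They therefore cannot exclude differences in handling between the arms, and they do not test any single gene. For the 2 genes of the interaction test, 4 of the 100 splits gave as many, the real one included, but the highest other gave 352, which points to a structure among the embryos whose nature was not tested. For the count of 4 gene lists called by camera, chance cannot be excluded. Of the 100 splits, 66 called as many, the real one included, and the highest other called 11, as list members vary together between embryos. This count does not test any single list. For the mitochondrial list, a chance split is argued against by the score per embryo, under the same assumption of independent embryos. The score differed by 0.27 within experiments (SE 0.07, permutation p = 2.1e-04), but by 0.14 without experiment 3 (permutation p = 0.181). Fry gave that list an adjusted p of 0.00753, and camera with an estimated correlation 0.0719.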

How the results depend on the processing

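The alternatives with a principal component, the library total or the Y-linked level as a term, with scaling without mitochondrial transcripts and without the embryo short of reporter counts were tests chosen after the data were seen; the others were fixed beforehand. Where no cause is named, the cause was not tested. Among genes called both as reported and under an alternative fit of genes, 0 had opposite signs. Spike-in scaling was not run, as there are no such rows, and the rule on shallow embryos removed 0 embryos. Genes lower and higher, 63 and 85 as reported, were 11 and 18 with factors from the oocyte list, 391 and 574 without a low-count filter (30691 genes tested), 37 and 23 without an experiment term, 1 and 2 in sums per experiment and arm (fewer samples), 22 and 56 over transcripts, and 219 and 141 with the first principal component as a term. DESeq2 gave 141 higher genes, limma-voom 98 lower and the number of genes detected as a term 118 lower. Leaving out 1 experiment, or the embryo short of reporter counts (64 lower), gave 9 (without experiment 1) to 64 lower and 14 (without experiment 1) to 136 (without experiment 2) higher genes. Experiment 1 alone gave 21 lower and 86 higher genes, experiment 3 alone 7 and 11, and experiment 2 alone 0 and 0 by edgeR, with 796 at an unadjusted p under 0.05, the only tool run on it.

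The embryo numbers do not pair embryos of the arms: 16 of 46 pairs had a correlation over 0.1 (median 0.052, -0.364 to 0.376) and 5 embryos correlated best with their own number. The replicate block on 92 embryos gave 8 lower and 11 higher genes, a mean of 0.061 for ribosomal proteins (adjusted p = 0.0182; adjusted p = 0.978 with an estimated correlation) and -0.065 for ribosome biogenesis (adjusted p = 0.170).

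Nr5a2 kept its sign in 24 alternatives (-1.69 to -1.07) and missed the threshold in experiment 2 alone (-1.13). The number of lists called, 4 as reported, was 2 with factors from the oocyte list, DESeq2, no experiment term, sums per experiment and arm, transcripts, the embryo short of reporter counts left out or the library total as a term, and leaving out 1 experiment gave 1 (without experiment 1) to 4. In sums, 1 of the 2, ribosomal proteins, was not among the 4. Ribosome biogenesis (-0.032) lost its call with factors from the oocyte list (0.034), DESeq2 (-0.026), no experiment term (0.019), transcripts (-0.057), the embryo short of reporter counts left out (-0.011) or the library total as a term (-0.015), had -0.073 (without experiment 2) to 0.014 (without experiment 3) with 1 experiment left out, where the call was lost without experiments 1 or 3, and turned to 0.026 in sums and to 0.18 in experiment 2 alone (adjusted p = 8.3e-07). Ribosomal proteins (0.064) passed in sums (0.11), without experiment 3 (0.16; 0.017 without experiment 1) and in experiment 2 alone (0.15), and oocyte transcripts in experiment 3 alone (-0.11). These calls were lost with an estimated correlation (adjusted p = 0.981, 0.923, 0.797 and 0.878, in that order). Without experiment 2, B1 (0.41) and B2 (0.62) passed, against 0.23 and 0.20 without experiment 1. In experiment 2 alone Rfc2 (-0.024), Pola2 (-0.34), mitosis (0.058) and chromatin modifiers (0.082) turned sign, and no list passed there with an estimated correlation (adjusted p = 0.797 for ribosome biogenesis and 0.662 for chromatin modifiers). Genes differing between experiments, 2 as reported, were 1 with median-of-ratios factors, 7 with library totals, 527 without a filter, 5 at 10 counts in 20 embryos, 10 with DESeq2, 1 with limma-voom, 7 with the principal component, and 0 (without experiment 1, by edgeR) to 1 with 1 experiment left out. Of 30 called genes named besides Nr5a2, 28 had 1 sign throughout. Genes named for the largest folds had to have 1 sign in all 3 experiments, so this count is no separate test. Over named genes 917 of 1175 values kept their side of the threshold and 9 changed sign, and over the other lists 431 of 456 kept it and 119 changed sign. Of simulated 1.5-fold changes at these library sizes 45.9% were called, and the shares of depth and of spread between embryos in that limit were not separated.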

Other observations

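The correlations and the covariation of the called genes were chosen as tests after the results were seen, and the test of shared sequence was set before its result.

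The genes that rose in knockdown embryos also vary together between control embryos. Over the 56 controls, after removing the mean of each experiment, the 85 higher genes had a mean pairwise r of 0.221, against a highest value of 0.050 in 10000 random sets matched on expression, and the 63 lower genes had 0.191 against 0.086. Both sets were called with these same controls, and genes that vary together tend to be called together. The random sets lack this, so part of the gap can come from the calling. Of the 8 higher genes compared with Lrtm1, Pam was the closest, with Pearson's r from 0.944 to 0.997 in the 6 groups of experiment and arm (rho at least 0.958; highest permutation adjusted p = 2.6e-04 for r and 5.1e-04 for rho over the 48 relations computed; r at least 0.853 without the 2 embryos farthest from the median). These 8 genes were picked from the 85 after their values were seen, so the adjustment does not cover that choice. The exchange factor gene Dock10 followed Lrtm1 with r from 0.811 to 0.976, the transcription repressor gene Bhlhe41 with 0.769 to 0.936, the GABA receptor subunit gene Gabra2 with 0.768 to 0.938, the adhesion receptor gene Pecam1 with 0.784 to 0.925, and Zfp101 with 0.783 to 0.946. For these 5 genes the lowest rho was 0.643 to 0.679, in the 7 controls of experiment 2, where it did not pass (exact permutation test, adjusted p = 0.122 to 0.145). Nras had r from 0.657 to 0.941, with an adjusted p under 0.05 in 5 of 6 groups. For Pecam1 the lowest r without the 2 farthest embryos was 0.385, so part of that relation rests on few embryos. Cdh6 was looser, with 0.376 to 0.955 (lowest r 0.165 without the 2 farthest embryos) and an adjusted p under 0.05 in 4 of 6 groups.

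A candidate explanation is that a state which differs between embryos without any knockdown sets the level of these genes, and that knockdown embryos are shifted along it, but the mean pairwise r of 0.221 prompted this idea and is no separate test of it. The first principal component of the most variable genes does not account for the calls: with it as a term, 63 of the 63 lower and 84 of the 85 higher genes stayed called. Reads shared between transcripts are argued against for this pair, since the leading transcripts of Lrtm1 and Pam, which hold 99.995% and 99.5% of the counts of these genes, have 0 distinct 31-mers in common in GENCODE M21. Which state this may be was not tested, and it is a hypothesis found on the same embryos.

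Embryos were also split by their counts of Y chromosome transcripts. At least 10 counts of Usp9y, Zfy1 and Zfy2 together were found in 28 of 56 control and 34 of 55 knockdown embryos (Fisher's exact p = 0.253), so the arms did not differ detectably at this cut. The counts were not scaled for library size, with 9 as the highest below the cut and 13 as the lowest above it. The cut is therefore no firm call of sex. With the Y-linked level as a term there were 68 lower and 87 higher genes, with 61 and 83 shared with the reported ones. The first principal component was computed over the most variable genes, after removal of differences between experiments, and held 19.8% of the variance of those genes.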
